A study of Mus musculus with 4 samples.

How the data were processed

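Single-cell RNA was measured in 4 libraries from mice bearing intracranial glioma: a CD45 sort and a GFP tumour sort, each from mice drinking NaCl or sodium propionate. The 3 count matrices used here (both CD45 libraries and the NaCl tumour library) hold raw UMI counts per gene and barcode, deposited as filtered matrices that the authors made with Cell Ranger (no version stated) on the mm10 build, per the submitters' processing notes. The chemistry was 10x 3' v3 per the labels. Of the propionate tumour library only the number of barcodes is used here. The CD45 matrices list 31053 genes and the tumour matrix 32285, with 30406 gene IDs in both. No gene symbol in them contains GFP, so the sorted protein's RNA was not followed.

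Barcodes were kept with at least 300 genes, at least 500 UMIs and at most 10% mitochondrial UMIs. The last limit removed 16.7% of NaCl CD45, 13.9% of propionate CD45 and 26.7% of NaCl tumour barcodes. In the CD45 libraries 8227 and 6878 barcodes passed the filters, of which Scrublet (in scanpy, seed 0) called 259 (3.15%) and 190 (2.76%) doublets, leaving 7968 and 6688 cells. In the tumour library it called 0 of 6018 and has not worked there. Counts were scaled to 10000 per cell and logged, and 2000 variable genes, 30 principal components and 15 neighbours fed Leiden clustering, at resolution 1.0 for the 2 CD45 libraries together, with T and NK cells clustered again, and 0.5 for the tumour library. Clusters took their "-like" names from the highest of 29 marker sets fixed before the data were examined, as were the filters, the 47 gene lists, the rule for named genes and the first set of alternatives. A cluster stayed unnamed, or took the plain T-like name among T and NK cells, when another set had more markers among its 10 leading genes. Shallow clusters without a marker of their set among those genes also stayed unnamed. Immune-led tumour clusters are those in which at least 5 of 10 leading genes stand at least 10-fold higher in the NaCl CD45 than in the NaCl tumour library, a definition chosen after the clusters were seen.

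With 1 library per group nothing was tested for significance. Shares carry exact binomial (Clopper-Pearson) intervals. Gene levels are UMIs summed over a class, and ratios of propionate over NaCl carry exact conditional binomial intervals. Lists are described by the median log2 ratio of members with at least 20 UMIs (interval from 2000 Poisson resamplings), the members at least 1.5-fold higher or lower, and the percentile of the median among 10000 random lists matched in 20 bins of expression. Which lists are described was chosen after their values were seen, 73 pairs of a list and a class. Classes needed at least 100 kept cells in each library. Genes were named by size where they had at least 50 UMIs over both libraries, at least 50 CPM in the higher library and at least 0.2 of the level of the highest class, and were not mitochondrial, ribosomal, haemoglobin, immunoglobulin, T cell receptor, sex-linked or predicted genes. They were ranked by the end of the interval nearest 0, with the first 5 higher and 5 lower in the 3 largest classes (monocyte/macrophage-like, microglia-like and NK-like) and the first 3 each way in the others. The rule also names 2 to 4 members of each list described and any detected gene for short-chain fatty acid receptors or transporters. In the tumour library it names the 10 genes with the highest CPM and the 5 leading genes per cluster. A few genes that the rule names are not reported here. Gene positions come from the GENCODE vM21 annotation, in which 180 of 180 named genes were found.

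Alternatives were a lenient cell filter (at least 200 genes, at most 20% mitochondrial), a strict one (at least 800 genes, 1500 UMIs, at most 5%), doublets kept, genes centred within each library, resolutions 0.5 and 2.0, classes from each cell's highest marker score, other denominators, scaling by the median of gene ratios, CPM without mitochondrial and ribosomal genes, the mean over cells, thinning of cells to 3024 UMIs (1991 NaCl and 1316 propionate CD45 cells have fewer and were left out; 14421 UMIs in the tumour library), other count minimums and random lists without matching. Added after the data were seen were clustering without 1040 genes that differ between the libraries, the mix of clusters held fixed within a class, and leaving out the 5 cells with most UMIs of a gene. The gene comparison was tested on simulated Poisson counts at the depth of each of 11 classes: intervals recovered 55% to 86.6% of genes changed 1.5-fold, 92.2% to 100% of those changed 2-fold and 100% of those changed 4-fold, and left out 0 for 3.76% to 4.39% of unchanged genes. The simulation holds no spread between cells or animals. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.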

Results

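The series measured single-cell RNA from brains of C57BL/6J mice that carried an intracranial GL261 glioma, a mouse glioma line of the same strain. Mice were 4 weeks of age, drank water with either sodium chloride (NaCl) or sodium propionate, a short-chain fatty acid that gut bacteria make from fibre, and were sampled on day 20 after tumour injection. Cells were separated on a Percoll gradient and sorted by flow cytometry, either for CD45, a surface protein of immune cells, from mice given GL261, or for green fluorescent protein (GFP), from mice given a GFP-expressing GL261 line. The 4 groups (2 sorts by 2 drinks) held 1 library each. The labels do not say how many mice each library pooled, so no difference below has a replicate check, and every interval covers counting error only. The NaCl CD45 library held 9874 barcodes with 54885739 UMIs (unique molecular identifiers, each counted as 1 RNA molecule), a median of 4287.5 UMIs and 1869 genes per barcode. The propionate CD45 library held 7994 barcodes with 50961338 UMIs and medians of 5031 UMIs and 2064 genes. The NaCl tumour library held 8214 barcodes with 167148157 UMIs and medians of 18440.5 UMIs and 4358 genes. The propionate tumour library listed 12692 barcodes; its counts were not analysed here, so no comparison of propionate with NaCl was made in tumour cells.

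The CD45 comparison asked which immune cells infiltrated the tumour-bearing brain under each drink. In the propionate library a smaller share of cells was CD4 T-like and CD8 T-like, and a larger share was microglia-like, border macrophage-like and cDC2-like (conventional dendritic cells of type 2). CD4 T-like cells, the helper T cells, made up 5.72% of 7968 kept NaCl cells (456 cells, 95% Clopper-Pearson interval 5.22 to 6.26) and 1.75% of 6688 kept propionate cells (117 cells, 1.45 to 2.09), 3.27-fold lower (log2 ratio -1.71, interval -2.02 to -1.41). Under the strict cell filter they were 4.58% and 2.34% (log2 ratio -0.97). CD8 T-like cells, the cytotoxic T cells, were 13.7% of NaCl cells (12.9 to 14.5) and 9.70% of propionate cells (9.005 to 10.4). Border macrophage-like cells, named after the resident macrophages of the meninges and vessels, were 3.45% (3.06 to 3.88) and 6.22% (5.65 to 6.83), a log2 ratio of 0.85 (0.63 to 1.07). Their name rests on 4 detected markers of 8. At resolution 0.5 no border macrophage-like or cDC2-like class was formed, and with libraries centred the border macrophage-like shares were 2.01% and 3.36%.

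Microglia-like cells, the resident macrophages of the brain tissue, were 15.4% of NaCl cells (14.6 to 16.2) and 19.4% of propionate cells (18.5 to 20.4), a log2 ratio of 0.33 (0.22 to 0.44). The cDC2-like cells were 2.82% and 4.28% (log2 ratio 0.60, 0.34 to 0.86). NK-like cells, innate cytotoxic lymphocytes, were 13.6% of NaCl and 11.3% of propionate cells (log2 ratio -0.26, -0.40 to -0.13), and proliferating T/NK-like cells 4.38% and 3.50% (-0.32, -0.57 to -0.08). Shares lay within counting error of each other for monocyte/macrophage-like cells (28.5% and 29.5%, log2 ratio 0.05, -0.04 to 0.14), regulatory T-like cells (4.14% and 3.77%, -0.14, -0.38 to 0.10), plasmacytoid DC-like cells (1.68% and 2.08%, 0.31, -0.05 to 0.66) and cluster T0 (2.62% and 2.89%, 0.14, -0.15 to 0.43). Cluster T0 scored highest on CD8 T cell markers (6 of 7 detected), but 0 of them are among its 10 leading genes. Those hold the gamma-delta T cell genes Trdc and Tcrg-C1, so the cluster is given by number. Summed over classes, lymphoid cells were 45.3% of NaCl cells (44.2 to 46.4) and 33.9% of propionate cells (32.8 to 35.0), and myeloid cells 54.5% (53.4 to 55.6) and 66.0% (64.8 to 67.1).

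All shares are shares of what the CD45 sort collected, so a lower lymphoid share raises every myeloid share. Within lymphoid cells alone, the NK-like and proliferating T/NK-like log2 ratios turned positive (0.16 and 0.09), and the CD8 T-like ratio was -0.08, while that of CD4 T-like cells was -1.29. Within myeloid cells alone, microglia-like cells were 28.3% and 29.4% (log2 ratio 0.053) and monocyte/macrophage-like cells 52.4% and 44.7% (-0.23), and the border macrophage-like and cDC2-like ratios were 0.57 and 0.32. Clustering without 1040 genes that differed between the libraries gave 6.55% and 2.38% CD4 T-like cells (log2 ratio -1.46), 11.8% and 8.24% CD8 T-like (-0.51), 13.8% and 11.3% NK-like (-0.28), 15.6% and 19.7% microglia-like (0.34), 2.52% and 3.98% border macrophage-like (0.66), 2.67% and 4.08% cDC2-like (0.61) and 14.9% and 14.5% monocyte/macrophage-like cells (-0.03). It also gave log2 ratios of -0.26 for proliferating T/NK-like, -0.12 for regulatory T-like and 0.29 for plasmacytoid DC-like cells and -0.02 for cluster T0.

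**Figure D1:**
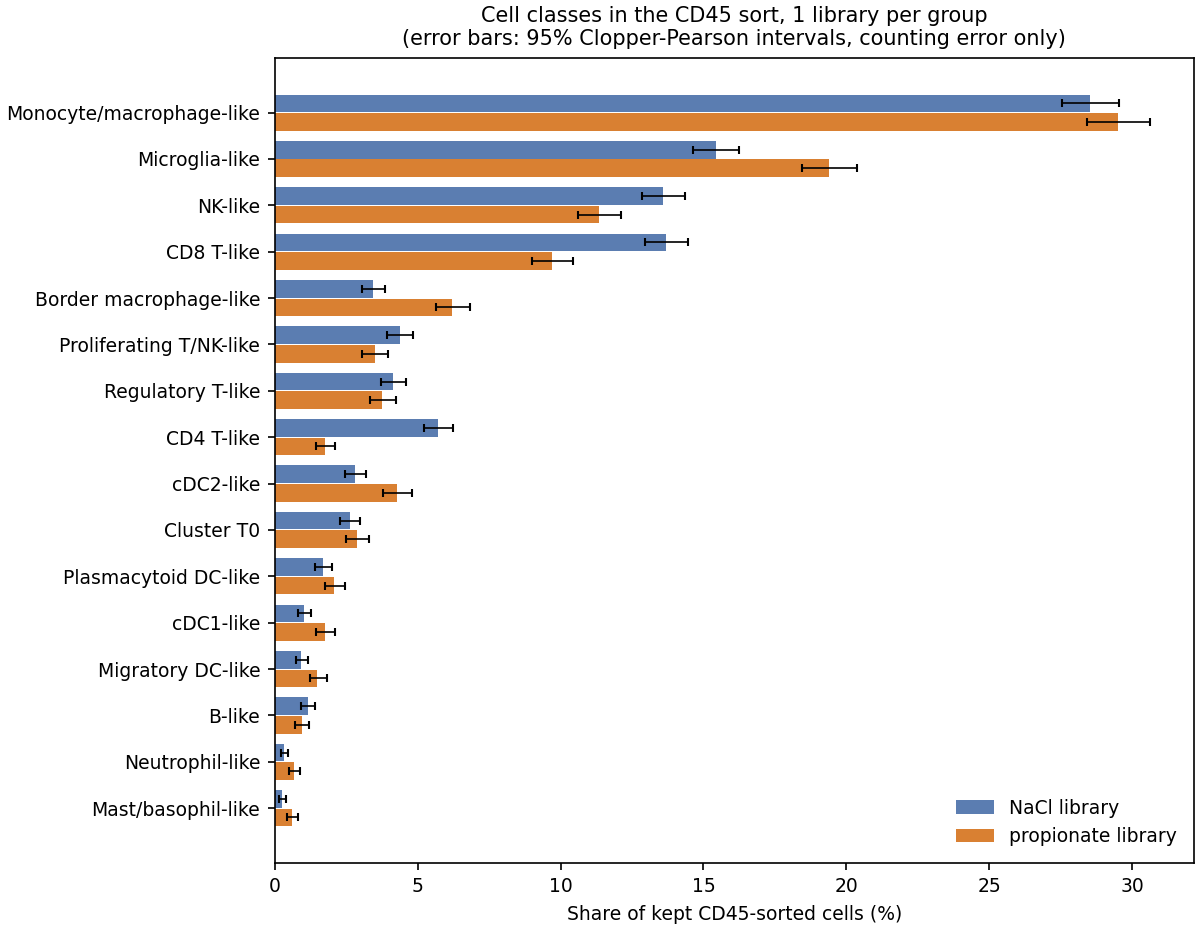
Share of kept CD45-sorted cells (%, x axis) in each cell class for the NaCl and the propionate library, 1 library each; error bars are 95% Clopper-Pearson intervals. CD4 T-like cells stand at 5.72% in the NaCl bar and 1.75% in the propionate bar, and border macrophage-like cells at 3.45% and 6.22%.

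Gene levels were compared within each class from UMIs summed over its cells and given as CPM (share of all UMIs of the class, times 10 to the power 6). In brackets, log2 ratios of propionate over NaCl stand with their 95% conditional binomial intervals, and list medians with intervals from Poisson resampling. In most classes, genes induced by type I interferons, the cytokines of antiviral responses, were lower in the propionate library. The median log2 ratio of the type I interferon response list was below 0 in 10 of 11 classes and 0.01 in cluster T0. In the monocyte/macrophage-like, microglia-like, NK-like, CD8 T-like, proliferating T/NK-like, regulatory T-like, CD4 T-like and cDC2-like classes, percentile 0 among 10000 random lists of matched expression held for that list. It did not stay below 0 everywhere: with cells weighted equally or thinned it was 0.04 or 0.00 in border macrophage-like cells, and under a stricter cell filter 0.05 in CD8 T-like cells. The median of the interferon gamma list was lowest in cDC2-like (-0.59), microglia-like (-0.47), monocyte/macrophage-like (-0.45) and border macrophage-like (-0.43), and in CD4 T-like cells (-0.44). It was near 0 in NK-like (-0.07), CD8 T-like (-0.06) and plasmacytoid DC-like cells (-0.08, -0.32 to 0.11), where members went both ways.

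**Figure D2:**
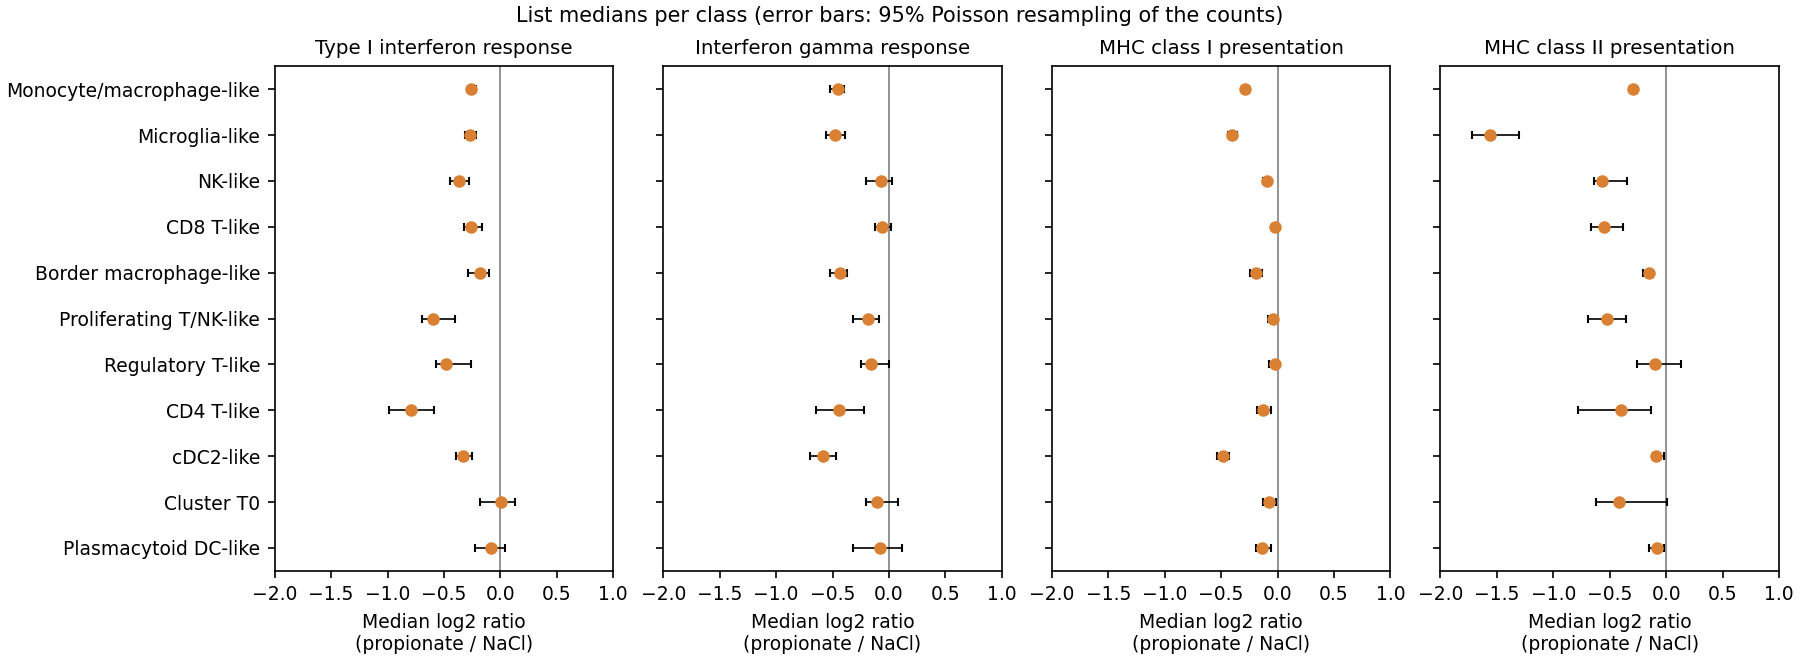
Median log2 ratio of propionate over NaCl (x axis) of 4 gene lists in each class with at least 100 cells per library; points are medians over list members and error bars 95% intervals from Poisson resampling of the counts. The MHC class II list stands at -1.56 in microglia-like cells and at -0.29 in monocyte/macrophage-like cells, and the type I interferon list below 0 in every class but cluster T0.

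Monocyte/macrophage-like cells of the propionate library held more Spp1, Lpl, Chil3, Fn1 and Emp1 RNA and less Ly6i, Ccl5, AW112010, C3 and Pla2g16 RNA than those of the NaCl library. Spp1, which encodes the secreted protein osteopontin (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050 in mm10), stood at 149 CPM in NaCl and 1113 CPM in propionate, 7.49-fold higher (log2 ratio 2.90, 2.84 to 2.97). Its UMIs came from 304 of 2274 NaCl cells and 778 of 1974 propionate cells. Lpl, lipoprotein lipase (ENSMUSG00000015568, chromosome 8, 68880491 to 68907448), stood at 39.3 and 142 CPM (1.85, 1.71 to 1.998), and Chil3, the chitinase-like protein Ym1 (ENSMUSG00000040809, chromosome 3, 106147554 to 106167564), at 534 and 1459 CPM (1.45, 1.41 to 1.49). Fn1, fibronectin, was 2.37-fold higher (1.24, 1.19 to 1.29) and Emp1, a membrane protein gene, 2.51-fold higher (1.33, 1.17 to 1.48). Ly6i, of the Ly6 family of surface proteins (ENSMUSG00000022586, chromosome 15, 74979534 to 74983430), was 2.58-fold lower in propionate, at 752 and 291 CPM (-1.37, -1.42 to -1.31). Ccl5, a chemokine that attracts T cells, was 2.33-fold lower (-1.22, -1.27 to -1.17), AW112010 1.74-fold lower (-0.80), complement C3 1.76-fold lower (-0.81) and Pla2g16, a phospholipase, 1.79-fold lower (-0.84).

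In the same class, antigen presentation and interferon lists were lower in propionate, and the suppressive macrophage, lipid-associated, pro-inflammatory and immediate early lists were higher. In these lists, and in those of every other class below, a difference between the preparations of the 2 libraries cannot be told apart from an effect of propionate. The interferon gamma list had a median of -0.45 (-0.52 to -0.39), with 0 of 17 members at least 1.5-fold higher and 4 lower, among them Gbp5 (-0.69), Iigp1 (-0.67) and the T cell chemokine Cxcl9 (1667 and 1081 CPM, -0.62, -0.66 to -0.59). The type I list (-0.26, -0.29 to -0.21) had 2 of 20 members lower by that size. Of its members, Ifi44 stood at -0.69 and Stat2, short of that size, at -0.43. MHC class I genes had a median of -0.29 (Nlrc5 -0.59, Psmb9 -0.36, Tapbp -0.33) and MHC class II genes of -0.29 (-0.32 to -0.28), with Ciita, the class II transactivator, at -0.48, H2-Ab1 at -0.35 and Cd74 at -0.33. The suppressive macrophage list had a median of 0.32 (0.29 to 0.40) with 8 of 19 members at least 1.5-fold higher and 0 lower, at percentile 100. The lipid-associated list stood at 0.28 (5 of 16 higher, 1 lower, Cst7 at -1.49). The pro-inflammatory cytokine list stood at 0.53 (0.45 to 0.61; 8 of 17 higher, 1 lower), with Il1a at 1.23 and the neutrophil chemokine Cxcl1 at 1.29. Immediate early genes, induced within minutes of a stimulus, had a median of 0.28 (Egr1 0.88, Egr2 0.77, Nr4a1 0.54), cholesterol synthesis 0.23 (Mvk 0.97, Cyp51 0.59, Idi1 0.50), antioxidant genes 0.14 (Srxn1 0.75, Gclc 0.53, Hmox1 0.49) and hypoxia genes 0.14 (Ndrg1 0.37, Ddit4 0.32, Mxi1 0.28).

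The T cell cytotoxicity list, most of whose genes belong to lymphocytes, was also lower in monocyte/macrophage-like cells of the propionate library (median -1.20, -1.37 to -1.01; 12 of 14 members at least 1.5-fold lower). Gzma stood there at 105 and 29.8 CPM and Nkg7 at -1.64, and Ccl5 belongs to this list as well. Ccl5 UMIs lay in 1185 of 2274 NaCl and 596 of 1974 propionate cells of the class, and Gzma UMIs in 528 NaCl cells. In the NaCl library Ccl5 had 9496 UMIs in the class against 11954 in all T classes, and Gzma 1350 against 50895. By these sums Ccl5 is not a gene of lymphocytes alone here. The class is made of 4 clusters: cluster 1, led by Ly6i and Cxcl9 among others, held 55.6% of its NaCl and 43.5% of its propionate cells, cluster 9, led by Cxcl2 and Il1b among others, 31.4% and 37.5%, cluster 16, led by Gpnmb and Apoe among others, 8.27% and 12.8%, and cluster 2, led by Chil3 and Fn1 among others, 4.75% and 6.18%. With the mix of clusters held fixed, the interferon gamma median was -0.34, the type I median -0.15, the MHC class II median -0.23, the pro-inflammatory median 0.43, the suppressive macrophage median 0.16 and the lipid-associated median 0.13.

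Microglia-like cells of the propionate library held far less RNA of the MHC class II antigen presentation genes. Cd74, the invariant chain of MHC class II (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652), stood at 5077 CPM in NaCl and 1071 CPM in propionate, 4.74-fold lower (-2.25, -2.28 to -2.21). H2-Eb1 stood at 962 and 206 CPM (-2.22, -2.30 to -2.15), H2-Aa at 1530 and 338 CPM (-2.18, -2.24 to -2.12) and H2-Oa at 126 and 50.9 CPM (-1.31, -1.48 to -1.15). Of the 10 members of the list, 7 were at least 1.5-fold lower and 0 higher (median -1.56, -1.72 to -1.30, percentile 0). The interferon gamma list had 6 of 17 members lower and 0 higher (-0.47, -0.56 to -0.39), led by Cxcl9 (199 and 55.1 CPM, -1.85, -2.0002 to -1.70), Ciita (-1.81) and Gbp2 (-0.81). In 5 cells lay 62.6% of the propionate Cxcl9 UMIs. Without the 5 cells with most UMIs of each library, the ratios of these genes were -2.82, -2.28 and -1.08. Type I interferon genes had a median of -0.27 (Irf7 -0.41, Rsad2 0.38) and MHC class I genes of -0.40 (H2-Q7 -0.70, Nlrc5 -0.66, H2-K1 -0.43).

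Higher in propionate microglia-like cells were Fkbp5 (2.58-fold, 1.37, 1.22 to 1.52) and Tsc22d3 (2.35-fold, 1.23, 1.10 to 1.37), both known targets of the glucocorticoid receptor. Also higher were Ddit4, an inhibitor of mTOR signalling (ENSMUSG00000020108, chromosome 10, 59949669 to 59951834; 25.4 and 78.2 CPM, 1.62, 1.39 to 1.86) and the antioxidant enzyme gene Srxn1 (1.63, 1.35 to 1.91). Besides Cd74 and H2-Oa, those lower were Cst7, a cysteine protease inhibitor (304 and 168 CPM, -0.85), Il2rg, the common cytokine receptor chain (-0.89), and Gbp2. Immediate early genes had a median of 0.62 (0.58 to 0.66), with 9 of 15 members at least 1.5-fold higher and 0 lower, among them Ier2 (0.94), Dusp1 (0.93) and Jun (0.79). Here too, a difference between the preparations cannot be told apart from an effect of propionate. G2/M genes, transcribed in dividing cells, had a median of 0.65 (0.51 to 0.77; 13 of 20 higher, 0 lower), at low levels such as 28.6 and 49.5 CPM for Mki67, 10.5 and 20.5 CPM for Ccnb2 and 15.9 and 29.9 CPM for Birc5. Their log2 ratios were 0.79, 0.97 and 0.91. With doublets kept they were 0.37, 0.47 and 0.47, and under the strict filter that of Mki67 was 0.16. Homeostatic microglia genes had a median of -0.09 (-0.12 to -0.05), with Sall1 at -0.23, Tmem119 at -0.20 and Fcrls at 0.64. Lipid-associated genes had a median of -0.09 (2 of 16 higher, 2 lower), with Apoe, a lipid carrier, at 6727 and 11440 CPM (0.77, 0.75 to 0.78) and Itgax at -0.83. The pro-inflammatory list stood at 0.15 (Cxcl2 0.93, Ccl5 -0.95, Il12b -2.61 from 53 and 10 UMIs), the antioxidant list at 0.16 (Hmox1 0.79, Txnrd1 0.48) and the hypoxia list at 0.18 (Slc2a1 0.41, Car9 -1.02 from 37 and 21 UMIs).

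MHC class II genes are not made by NK cells or mouse T cells. Their list was lower there as well (median -0.57 in NK-like and -0.55 in CD8 T-like cells, where Cd74 was at -0.71 and H2-Aa at -0.72), at a far lower level. Summed over the list, the genes stood at 534 and 374 CPM in NK-like cells against 19258 and 10225 CPM in microglia-like cells. Within the microglia-like class, cluster 5, led by Egr1, Tnf and Il1a among others, held 22.1% of NaCl and 28.6% of propionate cells, and cluster 4, led by homeostatic genes, 69.8% and 63.4%. Cluster 11, with the G2/M genes Hmmr and Cenpf among its leading genes, held 8.14% and 8.02%, so its share of the class was alike. With the mix of clusters held fixed, the MHC class II presentation median was -1.53, that of immediate early genes 0.37, of G2/M phase genes 0.16 and of pro-inflammatory cytokines and chemokines -0.078. The cytotoxicity list in microglia-like cells stood at -0.95 (11 of 13 members lower; Nkg7 -1.41, Gzma -1.12). Of its members, Ccl5 (-0.95, at the median) and Cst7 (-0.85) had UMIs in 355 and 581 of 1229 NaCl microglia-like cells, and Gzma in 294.

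**Figure D3:**
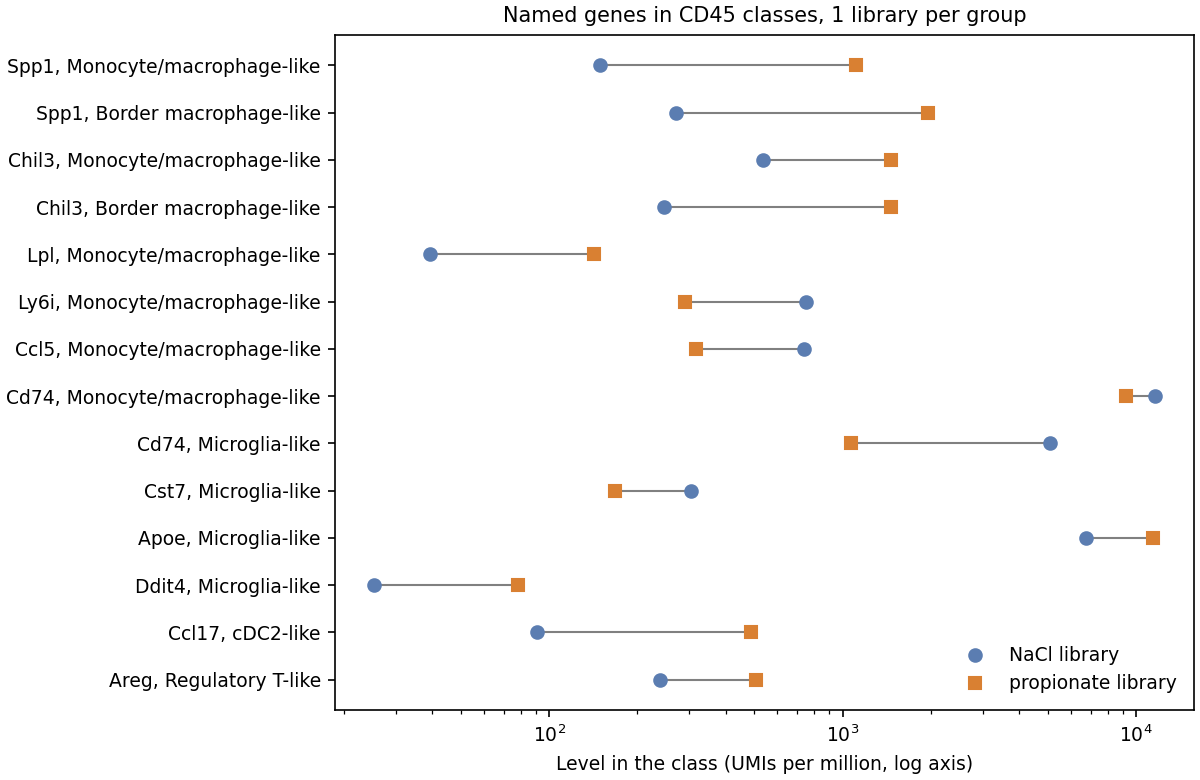
Level of 14 gene and class pairs in CPM of the class (x axis, log scale) in the NaCl library (circles) and the propionate library (squares), 1 library each. Spp1 in monocyte/macrophage-like cells lies at 149 and 1113 CPM, and Cd74 in microglia-like cells at 5077 and 1071 CPM.

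NK-like cells of the propionate library held more RNA of the granzymes Gzmg, Gzmf, Gzme and Gzmd, proteases of cytotoxic granules, and of the desmosome gene Dsc2, and less of Ifi44, Klra9, Pml, Sh2d1b1 and Ifi209. The level of Gzmf (ENSMUSG00000015441, chromosome 14, 56205263 to 56211417) was 295 CPM in NaCl and 3780 CPM in propionate (3.68, 3.60 to 3.76), that of Gzmg (chromosome 14, 56156582 to 56159579) 48.0 and 1335 CPM (4.80, 4.61 to 4.99), of Gzme 86.3 and 664 CPM (2.94, 2.80 to 3.10) and of Gzmd 225 and 1274 CPM (2.505, 2.41 to 2.60). These genes lie side by side and are near-identical copies, so their single values are uncertain. The UMIs were carried by few cells: those of Gzmg lay in 11 NaCl and 26 propionate cells, with 85.3% of the propionate UMIs in 5 cells, and those of Dsc2 (3.53) in 4 and 13 cells. Most of these UMIs lie in cluster T10, which these genes lead and which held 30 NaCl and 45 propionate cells. In NK-like cells outside T10, Gzmf was lower in propionate (397 and 88 UMIs, -1.75, -2.10 to -1.41) and Gzmg had 5 and 7 UMIs. Gzmd (1.39, 118 and 231 UMIs) and Gzme (2.0012, 57 and 170 UMIs) were higher there, but in few cells: 22 NaCl and 19 propionate cells for Gzmd and 11 and 11 for Gzme. With the mix of clusters held fixed, the log2 ratio of Gzmf was 2.44, of Gzmg 3.95, of Gzme 2.16, of Gzmd 1.70 and of Dsc2 2.39, and under the strict filter they were 2.23, 4.12, 1.498, 1.65 and 4.55. Without the 5 cells with most UMIs of each library they were 5.12, 6.95, 3.05, 3.20 and 3.64. The 5 NaCl cells left out held 86.8% of the Gzmf and 96.6% of the Gzmg UMIs, so few NaCl UMIs remain.

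Among the genes lower in propionate NK-like cells, Ifi44 (82.4 and 47.1 CPM, -0.81, -1.06 to -0.56), Pml (-0.78) and Ifi209 (-0.55) are interferon-induced, Klra9 (-0.66) is a receptor of the Ly49 family and Sh2d1b1 (-0.65) a signalling adaptor. The type I interferon list had a median of -0.37 (-0.45 to -0.28; 3 of 20 members at least 1.5-fold lower, 0 higher). Of its members, Ifi204 stood at -0.60 and Usp18, short of that size, at -0.57. The list median was -0.21 with the cluster mix fixed and -0.19 after thinning. The interferon gamma list stood at -0.07 (-0.21 to 0.03), with Cxcl9 at -1.17 from 43 and 16 UMIs, and Cxcl10 at 0.49 but -0.09 without the 5 cells with most UMIs and -0.98 under the strict filter. The cytotoxicity list had a median of -0.10 (2 of 15 higher, 0 lower), with Klrg1 at 1.31, Gzmk at 1.77 and Gzmb at 0.33, and -0.06 for Gzmb under the strict filter. For Gzmk, 54.9% of the propionate UMIs lay in 5 cells, and its ratio was 1.12 without the 5 cells with most UMIs of each library. The exhaustion list had a median of 0.06 (-0.03 to 0.35; 5 of 14 higher), with Pdcd1, the receptor PD-1, at 1.91 from 29 and 91 UMIs, Havcr2 at 1.05 and Tnfrsf9 at 0.70. Without the 5 cells with most UMIs of each library, these genes stood at 2.31, 0.79 and 0.41. Cholesterol synthesis genes had a median of 0.47 (0.35 to 0.65; 8 of 18 higher, 1 lower; Sqle 1.26, Idi1 0.96), heat shock genes of 0.33 (Dnajb1 0.54, Hspa1a 0.52, Hspa1b 0.49), glycolysis genes of 0.29 (Pgk1 0.48, Tpi1 0.37, Gapdh 0.32) and hypoxia genes of 0.24 (Ero1l 0.61, Ldha 0.24). Cells of T10 had a median of 17009 UMIs, against 3186 (NaCl) and 3714 (propionate) over the class. T10 held 2.77% of NaCl and 5.93% of propionate class cells, so it weighs more in class sums than in cell numbers. The part of these list medians that T10 carries is not given here.

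In CD8 T-like cells, higher in propionate were the serpins Serpina3f (16.8 and 51.7 CPM, 1.62, 1.25 to 2.01) and Serpina3g (0.92) and Ier5l (1.24). Lower were Ifitm1, an interferon-induced membrane protein (2681 and 1735 CPM, -0.63, -0.67 to -0.58), the receptor Klra5 (-0.76) and Gzmf (-0.63), which stood at 0.98 under the strict filter and 0.64 with classes from marker scores. Cytotoxicity genes had a median of -0.01 (-0.05 to 0.10), with 0 of 15 members at least 1.5-fold higher or lower (Gzma -0.51, Gzmb -0.27). Exhaustion genes had a median of 0.09 (Cd160 0.33, Lag3 -0.31) and immediate early genes of 0.21 (Atf3 0.86, Egr2 -1.11). The type I interferon median was -0.26 (-0.33 to -0.16) with Ifit1 at -0.56 and Ifi27l2a at -0.37, and in the interferon gamma list Cxcl10 stood at 0.60 and Iigp1 at -0.78. The strict filter gave 0.09 for Ifit1 and 1.22 for Iigp1. The makeup of this class differed: cluster T1, led by interferon-induced genes such as Ifit1 and Ifit3, held 426 of its 1091 NaCl cells and 28.5% of its propionate cells, and cluster T3 425 NaCl cells and 44.7% of propionate cells.

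CD4 T-like cells, 456 and 117, had the lowest type I interferon median of any class, -0.79 (-0.98 to -0.59), with 12 of 19 members at least 1.5-fold lower and 0 higher in propionate, among them the transcription factor Irf7 (-1.58) and Xaf1 (-1.26). The nucleic acid sensor Zbp1 (111 and 44.1 CPM, -1.34, -1.89 to -0.83) and Arl4c (-1.35) were lower. The strict filter gave -0.41 for Irf7, -0.65 for Xaf1, -0.75 for Zbp1 and -0.62 for Arl4c. Gzmd (-1.62) reversed, to 1.30 under the strict filter and 1.74 with marker scores. The exhaustion list had a median of -0.36 (4 of 14 lower, 0 higher; Tox -0.70, Cxcr6 -0.66). Helper cytokine genes had a median of 0.54 (0.40 to 0.61; 3 of 6 higher, 1 lower), with Csf2 at 344 and 550 CPM (0.68) and the T cell growth factor Il2 at 2.60, whose UMIs lay in 15 and 9 cells and which stood at -2.98 with libraries centred. The list stood at -0.08 under the lenient filter and -0.47 with libraries centred. The 3 genes ranked highest rest on few cells: Il3 (2 and 84 UMIs, in 1 and 3 cells), Sostdc1 (9 and 11 cells) and Tff1 (7 and 14 cells).

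Regulatory T-like cells had a type I interferon median of -0.48 (-0.57 to -0.26; 7 of 20 lower, 0 higher; Irf7 -0.95, Ifi27l2a -0.78) and a regulatory T program median of 0.02 (-0.05 to 0.06), with Izumo1r at -0.62 and the interleukin 2 receptor chain Il2ra at 0.27. Areg, the growth factor amphiregulin (ENSMUSG00000029378, chromosome 5, 91139599 to 91148432), was 2.13-fold higher in propionate, at 238 and 506 CPM (1.09, 0.90 to 1.28), Ermn 2.70-fold higher (1.44, and 2.53 under the strict filter and 2.40 after thinning) and Calca 4.63-fold higher (2.21), but 0.67 without its 5 highest cells. Nkg7 was 1.84-fold lower (-0.88). The cytokine genes Il13 (-4.71) and Il5 (-4.21) had their NaCl UMIs in 3 and 2 cells. The highest NaCl cell held 204 of the 219 Il13 UMIs, and that of Il5 held 88 of 89. Both genes belong to the helper cytokine list, whose median was -3.47 (6 of 6 members lower). That list had no median with at least 100 UMIs or under the strict filter. Proliferating T/NK-like cells had a type I median of -0.59 (-0.69 to -0.40; 10 of 19 lower, 0 higher; Ifi27l2a -0.75, Bst2 -0.59). They held less Cd200, an inhibitory ligand (-1.53, and -0.45 with libraries centred), Ifitm1 (2293 and 1022 CPM, -1.17, -1.22 to -1.11) and Ifng, interferon gamma itself (548 and 326 CPM, -0.75, -0.85 to -0.65), and more of the pro-apoptotic Bcl2l11 (0.93), Tsc22d3 (0.88) and Serpina3g (0.84). Their G2/M median was -0.02 (Cdc20 -0.40, Aurka -0.31) and their S phase median 0.13 (Rrm2 0.20, Slbp 0.19). Cluster T0 held more of the lymph node homing receptor Ccr7 (66.8 and 203 CPM, 1.61, 1.19 to 2.03), Themis (1.37) and Klf2 (0.75), with a naive and memory T median of 0.33 (0.22 to 0.46; 2 of 10 higher, 0 lower). It held less S100a4 (-1.45), Klra1 (-1.09) and Lgals1 (-1.07). The lenient filter gave 0.60 for Themis, -0.47 for S100a4 and -0.41 for Lgals1, thinning gave -2.32 for S100a4, and with libraries centred Themis stood at 0.03.

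Border macrophage-like cells shared the higher Spp1 (271 and 1959 CPM, 2.86, 2.73 to 2.98), Chil3 (247 and 1463 CPM, 2.57, 2.43 to 2.70) and Fn1 (1.46, 1.34 to 1.59) of monocyte/macrophage-like cells. With doublets kept, Chil3 stood at 1.37 and Fn1 at 0.52, and with cells weighted equally Spp1 stood at 1.82. Lower were Apol7c (-2.01), the lysosomal glycoprotein Gpnmb (-1.56) and Retnla, a marker of alternative activation (-1.47), of which Apol7c and Gpnmb stood at 0.17 with marker scores and Retnla at -0.72. Cholesterol synthesis genes had a median of 0.65 (0.47 to 0.86; 10 of 17 higher, 0 lower), with Sqle at 1.78. Hypoxia genes had a median of 0.29 (Pgk1 0.33, Ldha 0.33), suppressive macrophage genes of 0.14 (5 of 18 higher, 2 lower) and interferon gamma genes of -0.43 (-0.52 to -0.37; 6 of 17 lower, 0 higher; Gbp6 -1.26, Iigp1 -0.83). In the type I list, at -0.18 (-0.29 to -0.10), Ifi44 stood at -0.68 and Rsad2 at -0.89, and at 0.03 with doublets kept.

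The cDC2-like cells of the propionate library held more Ccl17, a chemokine for T cells that carry CCR4 (ENSMUSG00000031780, chromosome 8, 94810453 to 94812036; 91.1 and 488 CPM, 5.35-fold, 2.42, 2.19 to 2.65), Ramp3 (1.53) and Tnip3 (1.34, and 0.50 with marker scores). Less was found of Ly6i (-2.01), Pla2g16 (-1.50) and Cxcl9 (949 and 458 CPM, -1.05, -1.16 to -0.95). Ccl17 is also a leading gene of the cluster. The interferon gamma list had 8 of 16 members at least 1.5-fold lower and 0 higher (-0.59, -0.70 to -0.47; Iigp1 -1.10), the type I list 3 of 20 (-0.33; Ifi47 -0.82) and the MHC class I list 3 of 12 (-0.49, -0.54 to -0.43; Psmb9 -0.64, Tap2 -0.63). MHC class II genes had a median of -0.09 (-0.12 to -0.02) with 0 of 10 members past that size. Hypoxia genes had a median of 0.35 (4 of 13 higher; Ddit4 0.80, Vegfa 0.72). Plasmacytoid DC-like cells, 134 and 139, held more of the heat shock genes Hspa1b (1348 and 2802 CPM, 1.06, 0.96 to 1.15) and Hspa1a (1.08), near-identical copies whose split is uncertain (list median 0.55, 5 of 11 higher, 1 lower). They also held more Egr1 (1.66, and -0.52 under the strict filter) and Dusp1 (0.90) among immediate early genes (median 0.43, 4 of 14 higher). Arfgef2 (-1.25), Chst15 (-1.05) and Bdp1 (-0.93) were lower, of which Chst15 stood at 0.14 and Arfgef2 at -0.22 under the strict filter.

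The list of short-chain fatty acid receptors and transporters was slightly higher in monocyte/macrophage-like and microglia-like cells of the propionate library, and in other myeloid classes most of its genes lay within counting error. Hcar2, a receptor for hydroxy-fatty acids and butyrate, stood in microglia-like cells at 129 CPM in NaCl and 175 CPM in propionate (0.44, 0.32 to 0.56) and in monocyte/macrophage-like cells at 38.1 and 51.1 CPM (0.42, 0.25 to 0.60). Ffar2, the receptor for acetate and propionate, stood at 192 and 199 CPM in cDC2-like cells (0.05, -0.14 to 0.24) and at 14.8 and 19.7 CPM in monocyte/macrophage-like cells (0.41, 0.13 to 0.69). It had 2 and 2 UMIs in all microglia-like cells and 2 and 0 in all NK-like cells. The transporter gene Slc16a3 stood at 232 and 244 CPM in monocyte/macrophage-like (0.07), 66.4 and 87.8 CPM in microglia-like (0.40), 118 and 157 CPM in cDC2-like (0.41), 20.4 and 27.4 CPM in NK-like (0.42) and 39.0 and 35.7 CPM in CD8 T-like cells (-0.13). In plasmacytoid DC-like cells it had 21 and 10 UMIs (-1.22), and 0.59 under the strict filter. Slc16a1, another monocarboxylate transporter gene, had ratios of 0.49, 0.45 and 0.41 in monocyte/macrophage-like, microglia-like and NK-like cells and of 1.06 (0.40 to 1.75) in regulatory T-like cells. Slc16a7 stood at 0.12 and 0.31 in monocyte/macrophage-like and microglia-like cells, within counting error. In border macrophage-like cells Hcar2 stood at 0.37 (-0.04 to 0.79), Slc16a3 at 0.26, Slc16a7 at 0.17, Slc16a1 at -0.19 and Ffar2 at -0.44 (-1.28 to 0.41). Within counting error lay Ffar2 in regulatory T-like cells (1.09, -0.17 to 2.45), Hcar2 in cDC2-like cells (-0.27) and Slc16a1 in CD8 T-like (0.09), proliferating T/NK-like (0.26) and CD4 T-like cells (0.31) and in cluster T0 (-0.53). So did Slc16a3 in proliferating T/NK-like (0.00), regulatory T-like (-0.01) and CD4 T-like cells (-0.40) and in cluster T0 (-0.495). The remaining pairs of gene and class, Slc5a8 and Slc5a12 among them, had at most 16 UMIs over both libraries. The list had a median of 0.41 (0.14 to 0.50) over 5 members in monocyte/macrophage-like and 0.42 (0.27 to 0.53) over 4 in microglia-like cells, at percentiles 99.92 and 99.93, with 0 members at least 1.5-fold higher or lower.

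Enzymes of propionate and acyl-CoA metabolism had medians of -0.05 in monocyte/macrophage-like, 0.05 in microglia-like and 0.09 in NK-like cells, within their intervals (-0.18 to 0.13, -0.14 to 0.14 and -0.16 to 0.27). Members that stood off 0 were Echs1 (0.16 and 0.34 in monocyte/macrophage-like and NK-like cells), Bckdhb (0.69) and Bckdha (-0.26) in microglia-like and Pccb (1.08, from 25 and 44 UMIs) in NK-like cells. Histone deacetylases and acetyltransferases, enzymes on which short-chain fatty acids can act, had medians of 0.07, 0.11 and 0.04 in the 3 classes. Hdac9 stood at 0.77 and 0.53 in monocyte/macrophage-like and microglia-like cells from 30 and 50 and from 72 and 120 UMIs. Kat2b stood at -0.20 and Ep300 at -0.13 in monocyte/macrophage-like cells, and Hdac10 at 0.87 and Crebbp at -0.17 in NK-like cells, the latter at 0.08 under the strict filter. Fatty acid oxidation genes had medians of 0.05, 0.14 and 0.04 (Acadl -0.39, Acadm 0.26 and Hadha -0.24 in monocyte/macrophage-like, Acaa2 0.43 and Etfa 0.25 in microglia-like, Cpt2 -0.64 and Acads 0.41 in NK-like cells). Nuclear genes of oxidative phosphorylation had medians of 0.00, 0.01 and -0.04, with 0 of 23 members at least 1.5-fold higher or lower in any of the 3 classes. Among them were Ndufa4 (0.19), Atp5g1 (0.19) and Cox4i1 (0.09) in monocyte/macrophage-like, Sdhb (-0.27), Atp5b (0.20) and Atp5a1 (0.14) in microglia-like and Atp5g1 (0.31), Ndufa4 (-0.24) and Uqcrh (-0.16) in NK-like cells, where Atp5g1 stood at -0.01 under the strict filter.

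The GFP sort was examined in the NaCl library alone, over 6018 kept cells in 9 clusters. The main clusters were a dividing one, 2 without a cell type name and a small one led by hypoxia genes. In the 2 without a name, clusters 1 and 2, the highest marker set was that of oligodendrocyte progenitors (7 of 7 and 6 of 7 markers detected). They stay unnamed because another set had more markers among their 10 leading genes. The missing names depend on the setting: under the lenient filter, the strict filter and thinning, a large cluster took the oligodendrocyte progenitor name. Cluster 0, proliferating by its markers, held 30.9% of cells (29.7 to 32.1) and was led by the histone genes Hist1h2ae (431 CPM, 10.1-fold over other cells), Hist1h2ap and Hist1h1b and the mitotic genes Ube2c (862 CPM, 6.52-fold) and Nusap1. Cluster 1 held 34.6% (33.4 to 35.8), with small leads of the non-coding RNA genes Snhg4 (1.86-fold) and Dancr (1.97-fold), the DNA repair gene Ung (2.14-fold), Gm47015 and Rab26os. Cluster 2, 15.8% (14.9 to 16.7), was led by Lcn2, an iron-binding secreted protein (382 CPM, 7.63-fold), Enpp2 (5.22-fold), Ccn2 (6.47-fold), Sdc4 (3.29-fold) and the cartilage collagen gene Col2a1 (3.16-fold). Cluster 3, 3.07% (2.65 to 3.54), took the oligodendrocyte progenitor name (5 of 7 markers detected, fewer than in clusters 1 and 2) but was led by hypoxia genes: the glucose transporter Slc2a1 (1259 CPM, 15.5-fold), Car9 (226 CPM, 21.3-fold), Ero1l (1182 CPM, 12.03-fold), Bnip3 (10.6-fold) and, of another kind, the keratin gene Krt8 (11.6-fold). Cluster 4, 9.90% (9.16 to 10.7), had a median of 827.5 UMIs per cell, was led by Gm42418 (58567 CPM), AY036118, Lars2, Gpt2 and Rps26 and stays unnamed. Clusters 5, 6 and 7 (2.13%, 2.33% and 0.332%) were led by immune genes: cluster 5 by Il1b, Ctss, Tyrobp, Fcer1g and Plac8, cluster 6 by Gzma, Gzmb, Gzmc and the immunoglobulin genes Igkc and Ighm, and cluster 7, of 20 cells, by the chemokines Ccl3, Ccl4, Ccl6 and Ccl9 and the mast cell protease Mcpt1. Cluster 8 (1.01%) was led by Mgp, Igfbp7, Col1a2, Col4a1 and Ctla2a. It is fibroblast-like by its marker set, but Col1a2 was found in 42.6% of its cells, and Cldn5, a gene of endothelial junctions named after its value was seen, stood at 1207 CPM. At resolution 1.0 there were an endothelial-like and a fibroblast-like cluster, and after thinning an endothelial-like and no fibroblast-like one. The doublet caller marked 0 cells here and has not worked, so doublets remain in these clusters.

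Summed over the hypoxia list, cluster 3 stood at 7046 CPM (6960 to 7132, exact Poisson interval) against 1815 CPM over all cells, and over glycolysis genes at 11645 against 5238 CPM. Its MHC class I sum was 4404 CPM against 7792 CPM over all cells, and its MHC class II sum 1148 against 4689.7 CPM. Of the glioblastoma state lists, the mesenchymal-like list had the highest sum over all cells (7731 CPM), above the oligodendrocyte progenitor-like (828 CPM), astrocyte-like (625 CPM) and neural progenitor-like lists (517 CPM). Abundant genes set this order, with Lgals1 alone at 3216 CPM of the mesenchymal-like sum. The 10 genes with the highest levels were Tpt1 (7394 CPM), Hsp90ab1 (6669), Gm42418 (6491), Eef1a1 (6474), Actb (3873), Rack1 (3641), Ppia (3581), Npm1 (3548), Lgals1 (3216) and Malat1 (3085).

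**Figure D4:**
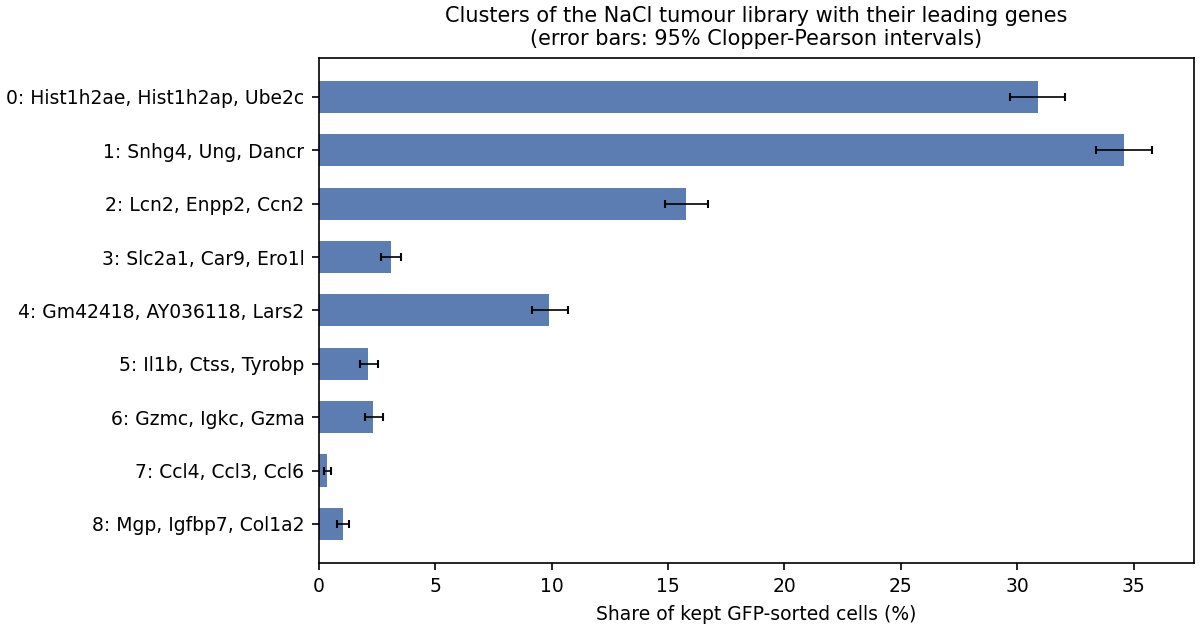
Share of kept GFP-sorted cells of the NaCl tumour library (%, x axis) in each of 9 clusters, labelled with 3 leading genes; error bars are 95% Clopper-Pearson intervals. Cluster 1 holds 34.6% and the proliferating cluster 0 30.9%, and cluster 3, led by Slc2a1, Car9 and Ero1l, holds 3.07%.

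Set side by side over shared gene IDs, the NaCl tumour and CD45 libraries come from different sorts and different injected lines. All 6018 tumour cells, those of immune-led clusters among them, and 8227 CD45 cells, here with called doublets, were summed. Glioma lineage genes stood high in the tumour sort: Olig1 at 242 CPM against 0.726 CPM in the CD45 sort, Sox10 at 199 against 0.314, Olig2 at 148 against 0.373, Sox2 at 143 against 0.235 and Nes at 145 against 1.53. Ptprc, which encodes CD45, stood at 5.27 CPM in the tumour and 1417 CPM in the CD45 sort. Tumour cells held more Lgals1 (3237 against 602 CPM), Vim (3029.8 against 463) and Mif (2150.3 against 499), and less B2m (1951 against 6360.1), H2-K1 (1672 against 4469.9) and Cd74 (1680 against 5682). Of the transporter genes in the short-chain fatty acid list, Slc16a3 stood at 93.8 and 107 CPM and Slc16a1 at 17.4 and 20.0 CPM. In the tumour clusters 0 to 3, Slc16a3 ranged from 74.6 CPM in cluster 2 to 228 CPM in cluster 3, the one led by hypoxia genes. The receptor genes Hcar2 (0.119 against 34.0 CPM) and Ffar2 (0.233 against 14.4) were found in the CD45 sort. The UMIs of Slc5a8, a sodium-coupled transporter gene, lay mainly in the tumour sort (2.65 CPM from 421 UMIs, against 1 UMI). Ffar3 had 0 UMIs in both, which allows up to 0.0232 and 0.0723 CPM.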

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

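Of the tests below, those on Cd4 CPM, on the CD4 share of lymphoid cells, on median UMIs, on MHC class II RNA in NK-like cells, on Ifng and on the share of granzyme UMIs in cluster T10 were chosen after their results were seen. Before the tests written ahead of their values were run, the concentration of granzymes in T10 and its cell numbers had been seen.

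Areg, the growth factor amphiregulin, was higher in propionate in regulatory T-like cells (log2 ratio 1.09) and lower in CD4 T-like cells (-1.01). Gzmd was higher in NK-like (2.505) and lower in CD4 T-like cells (-1.62), the latter from 12 NaCl and 5 propionate cells and with the opposite sign under 2 alternatives. These opposite directions drew attention, but the difference between classes was not tested. The GFP-sorted NaCl tumour library held 4.79% of cells (288 of 6018, interval 4.26 to 5.36) in clusters 5, 6 and 7, led by immune genes. No comparison treats these cells apart, the definition was chosen after the clusters were seen, and the limit that a count of 0 allows (0.0499%) would be passed by any few cells. Among barcodes left out of the propionate CD45 library by the filters or as doublets (1306), haemoglobin Hbb-bs had 503 UMIs, all in 1 barcode, against 1 UMI in the 1906 barcodes left out of the NaCl library.

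The lower share of CD4 T-like cells in propionate was weighed against technical explanations. Cd4 CPM summed over T classes was lower as well (281 and 139 CPM, log2 ratio -1.01, -1.10 to -0.92), which argues against CD4 T cells placed in other T classes, and the CD4 share of lymphoid cells was lower (12.6% and 5.16%, -1.29, -1.60 to -0.995), which argues against a lower lymphoid share alone. T cells of the propionate library had more UMIs each (medians 4382 and 4905, log2 ratio 0.16), against a loss of Cd4 calls by lower depth. After thinning, cells with a Cd4 UMI were 31.7% and 19.6% of T cells (-0.70, -0.93 to -0.47, with NK-like cells at 0.843% and 1.27%), and the upper end narrowly misses the bound of -0.5 set in advance, so depth in general stays open by that test. A difference between the pooled animals or between the preparations of the 2 libraries and an effect of propionate cannot be told apart with 1 library per group.

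The lower MHC class II RNA in microglia-like cells was weighed next. RNA from other cells would reach NK-like cells too, but the list's summed level differed there by 160.3 CPM against 9032 CPM in microglia-like cells, 1.77%. Macrophages counted as microglia would need abundant macrophage markers at 25.3% of their macrophage level, and over 12 such markers the upper quartile was 9.48% (median 4.01%). Ifng, whose product induces these genes, was lower over all kept cells (248 and 147 CPM, log2 ratio -0.75, -0.79 to -0.71), so less interferon gamma in the propionate library is a candidate explanation. That value partly follows from fewer T cells, no protein was measured, and a difference between animals stays open.

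The higher Gzmd, Gzme, Gzmf and Gzmg in NK-like cells was weighed last. Reads divided differently among near-identical copies would leave their sum alike, but the sum with Gzmc was higher in propionate (3479 and 11278 CPM, log2 ratio 1.70, 1.67 to 1.72). Few cells carry the signal: 5 propionate cells hold 65.1% of the Gzmf and 85.3% of the Gzmg UMIs, and 98.3% of the propionate UMIs of the 4 genes (82.1% in NaCl) lie in cluster T10, of 30 NaCl and 45 propionate cells. More T10 cells at an equal level would leave the level within T10 alike, but it was higher (4345 and 31846 CPM, log2 ratio 2.87), also without the highest 5 of 30 NaCl and 8 of 45 propionate cells (529.7 and 8871 CPM), a check chosen after the result was seen. Within T10, Gzmf UMIs lay in 10 NaCl and 26 propionate cells and Gzmg UMIs in 7 and 24. Leaving out the highest cells thus cuts deeper into the NaCl cells with these UMIs, and the check cannot show a higher level per such cell. These genes lead T10, so another mix of cells within it, or cells from 1 animal, may play a part and was not tested.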

How the results depend on the processing

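No paired analysis was possible because each group has 1 library. A value is called reversed where its sign changed and the reported interval left out 0, and moved where it otherwise left that interval. Sign changes where the interval spans 0, as for the microglia-like pro-inflammatory median with the cluster mix held fixed, are not counted as reversed. Of 105 alternative values of 11 class shares, 86 stayed within the counting interval, 17 moved and 2 reversed; of 3447 for 273 genes in their classes, 2880, 549 and 18; of 1006 for 73 list medians, 854, 146 and 6; and of 70 for the tumour library, 42, 28 and 0. All values that reversed follow by setting, with those that moved among the class share ratios, the interferon and MHC class II medians of the 3 main classes and the proliferating, immune-led and stromal shares of the tumour library, as log2 ratios of propionate over NaCl or percents; the cause was not tested. Strict cell filter: shares of microglia-like 0.22, regulatory T-like -0.41, CD4 T-like -0.97 and plasmacytoid DC-like cells -0.24 (reported 0.31, interval across 0); NK-like Cxcl10 -0.98, Gzmb -0.064, Atp5g1 -0.0064 and Crebbp 0.077, CD8 T-like Gzmf 0.98, Iigp1 1.22 and Ifit1 0.087, CD4 T-like Gzmd 1.30, plasmacytoid DC-like Chst15 0.14, Slc16a3 0.59 and Egr1 -0.52; medians of MHC class II in microglia-like cells -1.80, and of type I interferon in microglia-like -0.14 and CD8 T-like cells 0.046; tumour immune-led clusters 4.24% and proliferating 36.0%. Lenient filter: CD4 T-like helper cytokines -0.084, tumour proliferating 27.3%. Doublets kept: border macrophage-like Rsad2 0.026, monocyte/macrophage-like type I interferon -0.30 and MHC class II -0.27. Genes centred per library: cluster T0 share -0.29 (its reported interval spans 0), CD4 T-like Il2 -2.98 and helper cytokines -0.47. Resolution 0.5: monocyte/macrophage-like share 0.16 and MHC class II -0.28. Marker score per cell: shares of CD8 T-like -0.35, border macrophage-like 0.53 and regulatory T-like cells -0.40, CD8 T-like Gzmf 0.64, border macrophage-like Gpnmb 0.17 and Apol7c 0.17, CD4 T-like Gzmd 1.74, monocyte/macrophage-like interferon gamma -0.37 and MHC class II -0.24. Shares within the same lineage: monocyte/macrophage-like -0.23, microglia-like 0.053, NK-like 0.16, CD8 T-like -0.078, border macrophage-like 0.57, proliferating T/NK-like 0.094, regulatory T-like 0.28, CD4 T-like -1.29, cDC2-like 0.32 and cluster T0 0.56, where the smaller lymphoid total of the propionate library raises lymphoid ratios by construction. Scaling by the median of gene ratios: monocyte/macrophage-like MHC class II -0.27. Mean over cells: interferon gamma in monocyte/macrophage-like -0.54 and microglia-like cells -0.60, monocyte/macrophage-like MHC class II -0.27, microglia-like lipid-associated 0.013, border macrophage-like type I 0.039. Thinned cells: microglia-like interferon gamma -0.65 and type I -0.37, NK-like type I -0.19, border macrophage-like type I 0.0035; tumour immune-led 0.576%, proliferating 39.3% and stromal-named 0.354%, where shallow cells such as those of the immune-led clusters are left out by construction. Added after seeing the data, with the cluster mix held fixed: monocyte/macrophage-like interferon gamma -0.34, type I -0.15 and MHC class II -0.23, NK-like type I -0.21; and without the 5 cells with most UMIs, NK-like Cxcl10 -0.090. Clustering without genes that differ, also added, kept all 11 share ratios within their intervals. The monocyte/macrophage-like class itself was smaller there, at 14.9% and 14.5% of NaCl and propionate cells against 28.5% and 29.5%. Some settings form no such class and give no value: resolution 0.5 for border macrophage-like and cDC2-like cells, the strict filter for cluster T0, and marker scores for cluster T0 and proliferating T/NK-like cells, while helper cytokines in regulatory T-like cells have no median with at least 100 UMIs or under the strict filter. Of 73 list percentiles, 66 stayed alike without matching and 7 moved. Depth limits genes changed 1.5-fold most, of which simulated counts recovered 55% to 86.6% by class.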

Other observations

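The values here were chosen after they were seen, except Ifng in proliferating T/NK-like cells, which the rule on size names. Interferon gamma RNA was lower over all kept propionate CD45 cells (248 and 147 CPM), and within classes Ifng was lower in proliferating T/NK-like cells (-0.75) and regulatory T-like cells (75.5 and 28.3 CPM, -1.42) and higher in NK-like cells (151 and 177 CPM, 0.23, 0.08 to 0.38). In CD4 T-like cells it stood at 1995 and 2708 CPM (0.44), with 64.6% of the propionate UMIs in 5 cells, and at -0.40 without the 5 cells with most UMIs of each library. In CD8 T-like cells it stood at 565 and 658 CPM (0.22), with 34.9% of the propionate UMIs in 1 cell, and at -0.17 without those cells. Over all kept CD45 cells Spp1 stood at 136 and 599.5 CPM (2.14), the lipid carrier gene Apoe at 3833 and 5774 CPM (0.59), Cd4 at 99.9 and 39.0 CPM (-1.36), Gzma at 2199 and 1437 CPM (-0.61) and Gzmb at 1091 and 807 CPM (-0.44).

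Ddx3y, a gene of the Y chromosome, had 6654 and 7258 UMIs in the NaCl and propionate CD45 libraries and Xist, expressed from an inactive X chromosome, 3 and 3. In the NaCl tumour library the summed level of the sex-linked list was 2.06 CPM over all cells and 0.539, 0.305, 0.688 and 0.544 CPM in clusters 0 to 3. It was 193 CPM (157 to 233) in cluster 5 and 102 CPM (80.1 to 129) in cluster 6, both led by immune genes, 78.2 CPM in cluster 7 and 75.9 CPM (59.2 to 95.7) in cluster 8. In cluster 5 the summed MHC class II level was 29391 CPM, against 1148 to 5889 CPM in clusters 0 to 3.

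Classes with under 100 kept cells in a library were not compared gene by gene. Of these, cDC1-like cells were 1.03% and 1.75% of kept CD45 cells (82 and 117 cells), migratory DC-like 0.929% and 1.495% (74 and 100), B-like 1.15% and 0.942% (92 and 63), neutrophil-like 0.314% and 0.673% (25 and 45) and mast or basophil-like cells 0.264% and 0.598% (21 and 40). Cluster T12 (19 and 7 cells) stayed unnamed. Haemoglobin Hba-a1 had 4 UMIs in kept NaCl cells and 86 in kept propionate cells, the latter in 2 cells.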
